A study of Homo sapiens with 4 samples.

How the data were processed

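RNA was measured in 4 libraries of H1299 cells, 2 from a line that stably over-expressed GFP and 2 from a line that stably over-expressed SALL4. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a HyperPrep kit for paired-end sequencing. Per the submitters' processing notes, bcl2fastq 2.18, STAR 2.5 and DESeq2 were used. The genome build is given as hg38 in those notes and as hg19 in the series design, and the tables carry no coordinates that would settle it. The program that counted reads, its annotation and its strand setting are not given in the sources used here, so a gene and an overlapping or antisense neighbour may share reads.

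The deposited count table holds whole-number counts per gene and library, not normalised, per the file headers and the values. In the authors' deposited table of the comparison, the signal column is the mean over the 4 libraries of counts divided by size factors, per the file headers. The log2 column of the authors' deposited table is the log2 fold change of SALL4 over GFP, with its standard error beside it. The score column of the authors' deposited table is the Wald statistic, the fold change divided by that error. The p-value columns of the authors' deposited table are the raw p-value and the p-value adjusted by the Benjamini-Hochberg method. The version of DESeq2 behind that table is not given in the sources used here.

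Library totals ran from 17161448 to 30915450 counts, which sets the precision of genes with few counts. Of 28207 genes in the count table, 6531 had no count and 15871 passed edgeR's filterByExpr. Replicates had a Pearson correlation of 0.996 in log2 CPM across genes in each group, where genes are not independent replicates. Their counts differed by more than sampling noise, with a chi-square per degree of freedom of 2.1 for GFP and 2.67 for SALL4 over genes with at least 10 counts, so both were kept as separate samples.

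SALL4 was compared with GFP by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic, and values written with ± after a log2 fold change are this error. CPM values were scaled by TMM. The biological coefficient of variation was 3.13%. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which compares a list's genes with all others, and again with an estimated correlation. With the preset, camera takes its degrees of freedom from the number of genes, and with the estimate from the libraries. Of 40 gene lists fixed before the data were examined, 39 had a member in the count table and 34 had at least 5 tested genes and were tested. Of 985 list entries, 940 matched by symbol, 30 by an older symbol and 15 did not match. The list of genes encoded by mitochondrial DNA was not analysed here.

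The genes named in the text were chosen by a rule fixed before the data were examined. They are the SALL family, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1, both SALL4 libraries beyond both GFP libraries and an assigned gene symbol, and up to 4 members of each described list with the smallest p. Some genes that the rule selects are not reported here. Genes named outside the rule are said to be so.

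The alternatives tried were RLE and upper-quartile scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, each library left out in turn, a test against a log2 fold change of 1, fry for the lists and SALL4 left out. A correction for GC content, thinning to equal depth and a 2-fold minimum were added after seeing the data. The procedure was tested on simulated data with 200 changed genes among 15871. At changes of 1.25, 1.5, 2 and 4-fold, edgeR called 44%, 68%, 96% and 100% of the changed genes, and 7.78% of its calls were unchanged genes. DESeq2 called 38%, 64%, 76% and 96%, and 0% of its calls were unchanged genes. In the data edgeR called 6038 genes, far more than the simulation changed, so these rates may not carry over. A simulated shift of -0.3 in 1 list was called by camera with the preset correlation and not with the estimated one. The test with an estimated correlation thus missed a true shift in genes simulated as independent of one another. A call lost with it cannot by itself decide against a list. The simulation does not cover lists whose genes are correlated, so it does not set aside a call lost there.

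Coordinates and the GC content of transcripts, introns and flanking DNA came from a GRCh37 annotation, and RNA classes and gene order from RefSeq. These steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.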

Results

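The series holds 4 RNA-seq libraries from H1299, a human cell line established from a non-small-cell lung cancer. A pair of stable lines was compared, 1 carrying a GFP construct as the control and 1 carrying SALL4, a zinc-finger transcription factor of embryonic stem cells and germ cells that is silent in most adult tissues and returns in some tumours. Each line is represented by 2 libraries of total RNA from which ribosomal RNA had been removed. The gene count table gave totals of 19968100 and 24016828 counts for GFP replicates 1 and 2, and 17161448 and 30915450 for SALL4 replicates 1 and 2. Between 19644 and 20346 genes had a count in a library. The comparison asks which transcripts differ in level between the line that over-expresses SALL4 and the line that over-expresses GFP. Nothing in the labels says that the replicates came from separate cultures. The p-values of single genes thus measure only the spread between these samples, which may be technical. List p-values at the preset correlation take genes rather than libraries as their units. With 1 line per construct, none of these p-values covers the spread between lines.

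SALL4 itself was higher in both libraries labelled with it. Its counts were 29 and 31 in the GFP libraries and 1199 and 2360 in the SALL4 libraries, or 1.38 ± 0.124 and 72.7 ± 4.34 CPM (normalised counts scaled to library size, mean ± SD, n = 2 each). The log2 fold change was 5.73 ± 0.11 (SE), with an adjusted p of 2.13e-37 in edgeR's quasi-likelihood test. The count table does not separate the transgene from the endogenous gene, which lies on the reverse strand of chromosome 20 from 50398870 to 50419060 in the GRCh37 annotation. Both relatives of SALL4 that were tested were also higher, over all genes and adjusted over the list alone. SALL3 was at 54.5 and 48.3 CPM in the GFP libraries and 77.2 and 76.3 CPM in the SALL4 libraries, a log2 fold change of 0.58 ± 0.058, and SALL2 from 8.03 ± 0.749 to 11.5 ± 0.627 CPM, a log2 fold change of 0.50 ± 0.11. SALL1 had 0 counts in all 4 libraries.

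Many transcripts differed between the lines, most of them by a small amount. Of 15871 genes tested, 6038 passed an adjusted p of 0.05, 2911 higher and 3127 lower with SALL4. The median change of these genes was 1.24-fold, and 79.1% of them changed by at most 1.5-fold. At least 2-fold changes beside the adjusted p were seen for 324 genes that rose and 214 that fell. The CPM values of the groups did not overlap in 66.9% of the genes tested, where chance gives 33.3% for 2 libraries against 2. DESeq2 on the same counts called 3331 genes, 1464 higher and 1867 lower. Scaling by the upper quartile called 3785 genes higher and 2307 lower, or 62.1% higher against 48.2% with TMM scaling.

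Among genes with a mean log2 CPM of at least 1, the largest rises besides SALL4 were in genes that the GFP line transcribed at a low level. RSPO4, a secreted enhancer of WNT signalling, went from 0.474 ± 0.0971 to 5.87 ± 0.726 CPM, a log2 fold change of 3.57 ± 0.26 with an adjusted p of 1.18e-15. The protein kinase gene ALPK2 rose by 2.86 ± 0.21 and JCAD, which encodes a cell junction protein, by 2.46 ± 0.19 on the log2 scale. The imprinted zinc-finger gene PEG3 rose by 2.36 ± 0.27, the transcription factor gene STAT6, which acts downstream of interleukin-4, by 2.33 ± 0.21, the laminin gene LAMC3 by 2.24 ± 0.13 and the non-muscle myosin gene MYH14 by 2.22 ± 0.18. CYP4F35P rose by 2.19 ± 0.28, but it is a pseudogene whose reads may be split with its relatives, so that its value is uncertain.

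Above the same level, the largest falls were in genes that the GFP line expressed at low to moderate levels. NPAS2, a circadian transcription factor related to CLOCK, went from 25.5 ± 0.146 to 0.814 ± 0.166 CPM, a log2 fold change of -4.90 ± 0.15 and an adjusted p of 3.76e-29. IGFBP4, which binds insulin-like growth factors outside the cell, was 13.1-fold lower with SALL4, a log2 fold change of -3.71 ± 0.15. The chromodomain gene CDYL2 changed by -3.65 ± 0.29, the calcium channel gene CACNA1A by -3.64 ± 0.24 and GALNT14, an enzyme that starts O-linked glycosylation, by -3.34 ± 0.19. The adhesion gene LSAMP changed by -3.27 ± 0.18 and the transmembrane collagen gene COL13A1 by -3.23 ± 0.17. GASK1B changed by -3.05 ± 0.18, NHS by -3.00 ± 0.24 and PLA2G7, which encodes a lipase that inactivates platelet-activating factor, by -2.69 ± 0.22.

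**Figure D1:**
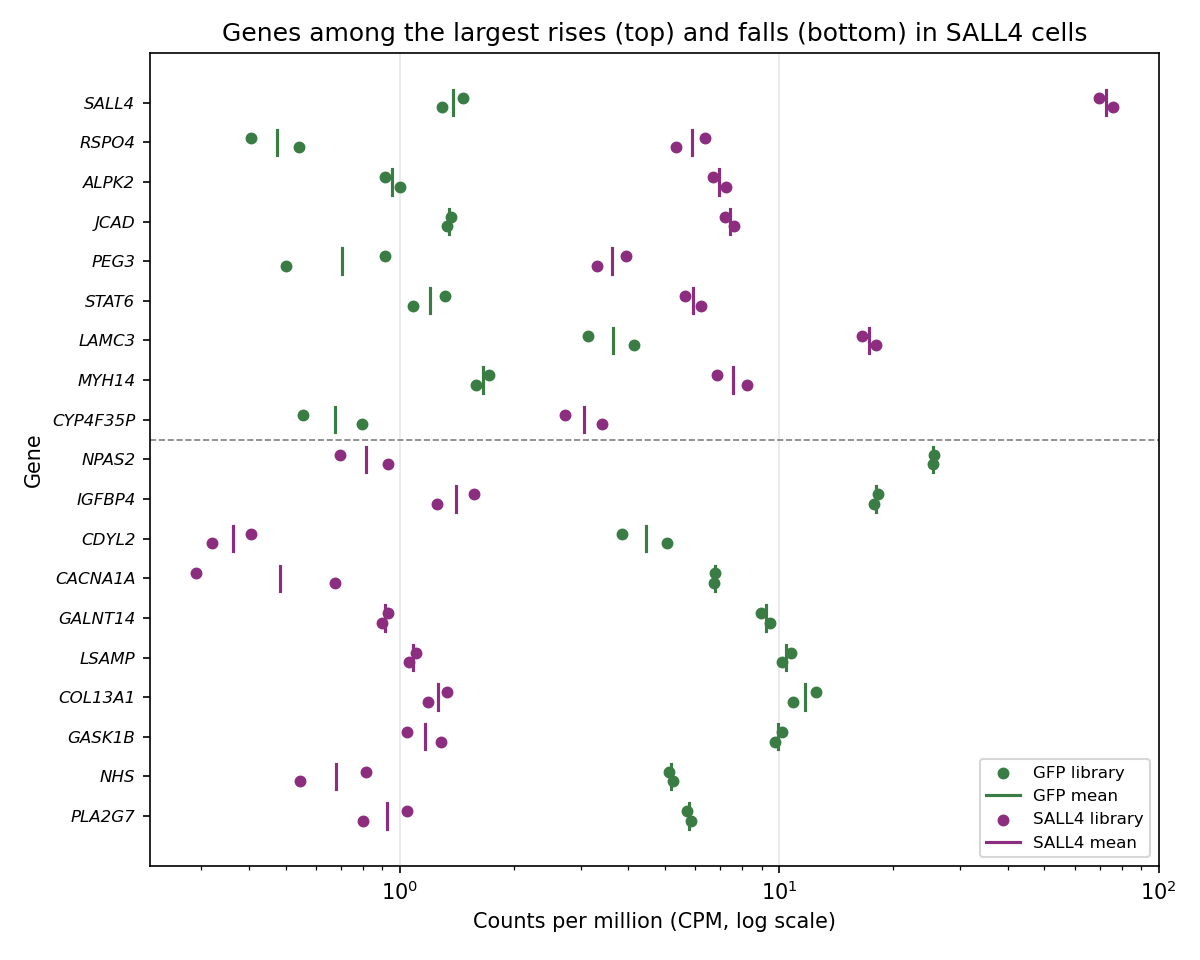
Normalised counts scaled to library size (CPM) on a log scale (x axis) of genes among the largest rises (above the dashed line) and falls (below it) at a mean log2 CPM of at least 1, 1 point per library and a vertical tick at each group's mean of 2 libraries. SALL4 went from 1.38 to 72.7 CPM and NPAS2 from 25.5 to 0.814 CPM. In each gene drawn the SALL4 and GFP points do not overlap, which the rule for choosing the genes required.

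Genes of DNA replication and of histone supply were lower in the SALL4 line by small amounts. Of 22 histone genes tested, 17 fell, 1 rose and 4 were not called. H3C4 changed by -0.57 ± 0.056, H4C5 by -0.65 ± 0.066 and H2BC5 by -0.44 ± 0.050 on the log2 scale. The rise was in the linker histone gene H1-5, at 0.31 ± 0.048, named after its value was seen. Adjusted over the list alone, 18 histone genes fell and 1 rose. Of 30 genes of DNA replication and repair, 17 fell and 2 rose, or 19 and 2 adjusted over the list alone, and DESeq2 called 11 lower and 1 higher. The rises were also down to 1 without GFP replicate 1, GFP replicate 2 or SALL4 replicate 2. RRM1, a subunit of ribonucleotide reductase, changed by -0.35 ± 0.049, and the replicative helicase genes MCM5 and MCM6 by -0.27 ± 0.048 and -0.26 ± 0.046. POLE, the catalytic subunit of DNA polymerase epsilon, was among the members that rose, at 0.15 ± 0.048, and was named after its value was seen. Both lists were lower relative to other genes in limma's camera test, with adjusted p of 0.000439 for the histones and 0.000666 for replication. Neither call held with an estimated correlation (camera adjusted p = 0.612 for each), a test that also missed a simulated shift of -0.3. That correlation was 0.0105 for the histones and -0.00383 for replication, against the preset 0.01. Correlation among the genes therefore does not account for the lost calls. The test with an estimated correlation takes its degrees of freedom from the libraries, not from the number of genes. Histone genes are close copies of one another, and their counts may be split among them.

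Genes of mitosis went partly the same way, without a call for the list. CCNB2, a mitotic cyclin, changed by -0.55 ± 0.050, and the mitotic kinesin genes KIF23 and KIF11 by -0.31 ± 0.045 and -0.28 ± 0.045. Shifts shared by the genes of a chromosome, described further below, were not taken out of these values. Of 30 genes of the cell cycle and mitosis, 13 fell, 3 rose and 14 were not called, over all genes and also adjusted over the list alone, and the list did not pass (camera adjusted p of 0.107). Without GFP replicate 2, 9 fell and 1 rose. Of 47 genes of the cytosolic ribosome, 25 fell and 5 rose, and the same numbers held adjusted over the list alone, against 20 and 3 without GFP replicate 1 or GFP replicate 2. RPS19 changed by -0.32 ± 0.043 and RPL4 by -0.30 ± 0.041. The ribosomal list was lower with a camera adjusted p of 0.0126, which became 0.0557 without GFP replicate 1 and 0.612 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes, which can take part of their reads.

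Genes of glycolysis and the response to hypoxia were lower in the SALL4 line. Of 28 genes tested, 17 fell, 3 rose and 8 were not called, and the same numbers held adjusted over the list alone. BNIP3, a mitophagy receptor induced by hypoxia, changed by -0.89 ± 0.063, the neuronal enolase gene ENO2 by -0.74 ± 0.061, the glucose transporter gene SLC2A1 by -0.68 ± 0.056 and the lactate dehydrogenase gene LDHA by -0.47 ± 0.043. The members that rose, named after their values were seen, were EGLN3, an oxygen-sensing prolyl hydroxylase, at 1.70 ± 0.35, the peptide hormone gene ADM at 0.63 ± 0.11 and the aldolase gene ALDOA at 0.13 ± 0.047. The list passed the camera test with an adjusted p of 0.000666 (adjusted p = 0.612 with an estimated correlation). That correlation was 0.0491, above the preset value, so it may have contributed to the lost call. Nuclear genes of oxidative phosphorylation, with 14 of 40 lower and 3 higher over all genes and adjusted over the list alone, did not pass (camera adjusted p of 0.22). ATP5F1A, a subunit of ATP synthase, changed by -0.50 ± 0.045 and the complex I gene NDUFV2 by -0.35 ± 0.060, while the complex IV gene COX6A1 rose by 0.21 ± 0.045. For that list 8 fell and 5 rose with upper-quartile scaling, 8 and 2 with DESeq2, 7 and 4 without GFP replicate 1 and 8 and 2 without GFP replicate 2.

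Receptors of adhesion and migration were mostly lower. Of 21 tested, 14 fell, 4 rose and 3 were not called, with the same numbers adjusted over the list alone. NRP1, a co-receptor for semaphorins and vascular endothelial growth factor, changed by -1.91 ± 0.11, the protocadherin gene PCDH7 by -1.15 ± 0.094 and the integrin gene ITGA4 by -0.50 ± 0.052. ITGAV rose by 0.45 ± 0.044, and ITGA2, ITGA5 and L1CAM, named after their values were seen, were higher by 0.32 ± 0.055, 0.12 ± 0.050 and 0.95 ± 0.32. The rises numbered 2 with DESeq2 and without GFP replicate 1, GFP replicate 2 or SALL4 replicate 2. The camera adjusted p was 0.0179, which became 0.0582 without SALL4 replicate 1 and 0.612 with an estimated correlation.

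The tested genes of a list of inflammatory cytokines and NF-kB targets were mostly higher in the SALL4 line. Of its 26 members, those that did not pass the count filter were all cytokines or chemokines. Of 15 tested, 9 rose, 1 fell and 5 were not called, and the same numbers held adjusted over the list alone. The adhesion receptor gene ICAM1 rose by 1.63 ± 0.093 and BIRC3, an inhibitor of apoptosis, by 0.67 ± 0.044. The chemokine gene CCL2 had 2 and 2 counts in the GFP libraries and 58 and 103 in the SALL4 libraries. The ratio of summed counts, scaled by the summed library totals without TMM, was 36.8. Its exact 95% interval from 14.1 to 137.0 covers counting error only. LIF, a cytokine of the interleukin-6 family, fell, at -1.32 ± 0.10. Genes that feed back on the NF-kB pathway, named after their values were seen, were among the rises, with NFKBIA at 0.56 ± 0.065, TNFAIP3 at 0.82 ± 0.089, NFKB2 at 0.65 ± 0.052 and RELB at 0.63 ± 0.059. The camera adjusted p was 0.000666 (adjusted p = 0.737 with an estimated correlation). That correlation was 0.321, well above the preset value. Unlike for the histone and replication lists, correlation among the genes may therefore have contributed to the lost call. The call of this list with the preset is uncertain for that reason. IL6 had 0 counts in all 4 libraries and CXCL8 had 2, 0, 0 and 0 counts in GFP replicates 1 and 2 and SALL4 replicates 1 and 2, both named after their counts were seen.

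**Figure D2:**
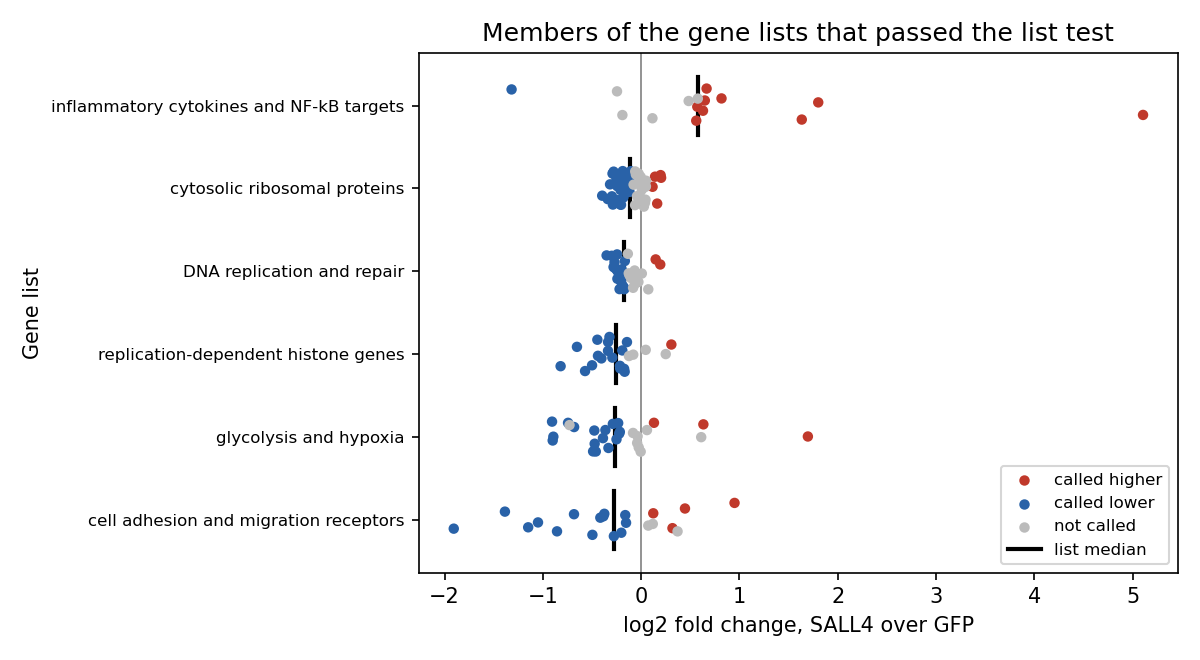
Log2 fold change of SALL4 over GFP (x axis) for each tested member of the 6 gene lists that passed the camera test (y axis), with members called higher in red, called lower in blue and not called in grey, and the list median as a black bar. The medians run from -0.278 for adhesion receptors to 0.576 for inflammatory genes, where CCL2 is the point farthest to the right. The lists passed with the preset correlation, and none of them did with an estimated one.

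Genes that earlier studies tie to SALL4 moved in both directions. Of 19 tested, 6 rose and 7 fell, or 7 and 7 adjusted over the list alone, 4 and 4 with DESeq2, 6 and 4 without GFP replicate 2 and 5 and 4 without SALL4 replicate 2, and the list did not pass (camera adjusted p of 0.924). Its median was 0.10, or 0.04 without GFP replicate 2, 0.04 without SALL4 replicate 1 and -0.015 without SALL4 replicate 2, while its mean was -0.02 and the test pointed down. IGF1R rose by 0.48 ± 0.047 and the oncogene MYC by 0.35 ± 0.046, whereas the cyclin gene CCND1 changed by -0.40 ± 0.043. Among 9 pluripotency and early germ cell factors tested, 2 rose and 3 fell (camera adjusted p of 0.901), over all genes and adjusted over the list alone, and the test pointed down while the median was 0.10 and the mean 0.07. That median was -0.11 without GFP replicate 2, -0.03 without SALL4 replicate 1, 0.16 without GFP replicate 1 and 0.29 without SALL4 replicate 2. With DESeq2 it was -0.26, taken only over members to which DESeq2 gave an adjusted p. KLF4 fell, at -1.26 ± 0.094, as did PRDM1, at -0.68 ± 0.11, and LIN28B, a repressor of let-7 microRNAs, rose, at 0.35 ± 0.047. DPPA2, a factor of pluripotent and germ cells, rose by 1.61 ± 0.34, from 9 and 14 counts to 22 and 57, with an adjusted p of 0.00017 that became 0.0515 without SALL4 replicate 2. Without that library 1 member rose and 2 fell. NANOG, named after its counts were seen, had 1, 0, 0 and 0 counts. Of 14 cancer-testis genes tested, 6 rose and 3 fell, or 7 and 3 adjusted over the list alone (camera adjusted p of 0.47), against 8 and 1 with upper-quartile scaling, 4 and 1 with DESeq2 and 5 and 1 without GFP replicate 1 or SALL4 replicate 2. MAGEA1 went up by 1.98 ± 0.094, the cohesin gene STAG3 by 0.67 ± 0.053 and PRAME by 0.22 ± 0.046, while MAGEA6 fell, at -0.25 ± 0.057, and MAGE family members share sequence, so that reads may be split among them.

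Partners and related regulators of chromatin changed in single members. Of 17 genes of the NuRD and histone deacetylase complexes, to which SALL4 is known to bind, 3 rose and 4 fell (camera adjusted p of 0.788), against 6 and 4 with upper-quartile scaling. RBBP7 changed by -0.37 ± 0.049, GATAD2B by 0.28 ± 0.044 and MBD2 by -0.25 ± 0.050. Of 10 enzymes and readers of DNA methylation, 1 rose and 4 fell, or 2 and 4 adjusted over the list alone and 0 and 3 without GFP replicate 1, 3 and 4 without SALL4 replicate 1 and 0 and 4 without SALL4 replicate 2 or with DESeq2 (camera adjusted p of 0.272). The dioxygenase genes TET1 and TET2 changed by -0.62 ± 0.066 and -0.33 ± 0.053 and UHRF1 by -0.27 ± 0.047. Of 15 Polycomb genes, 6 rose and 2 fell (camera adjusted p of 0.42), with CBX7 at 0.46 ± 0.088, CBX2 at 0.50 ± 0.10 and SUZ12 at -0.24 ± 0.050. DESeq2, and edgeR without GFP replicate 1, each called 3 Polycomb genes higher and 1 lower. Of 33 HOX genes, 7 rose and 2 fell (camera adjusted p of 0.484), with HOXC6 at 0.59 ± 0.060 and HOXC8 at 0.41 ± 0.056, against 9 and 0 with upper-quartile scaling, 4 and 0 with DESeq2, 6 and 0 without GFP replicate 1, 4 and 2 without GFP replicate 2 and 6 and 1 without SALL4 replicate 2. The NuRD, Polycomb and HOX counts were the same adjusted over the list alone.

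Epithelial, mesenchymal and matrix genes did not move as groups. Of 13 epithelial genes tested, 3 rose and 2 fell (camera adjusted p of 0.54), and the median of 0.17 and the mean of -0.07 differed in sign. That median was 0.05 without GFP replicate 2 and 0.04 without SALL4 replicate 2, and 5 rose and 2 fell with upper-quartile scaling. The hemidesmosome genes ITGB4 and LAMB3 changed by -1.66 ± 0.084 and -1.47 ± 0.086, while the tight junction gene OCLN rose by 0.47 ± 0.058 and the keratin gene KRT8 by 0.32 ± 0.046. CDH1, the epithelial cadherin, named after its counts were seen, had 0 counts in all 4 libraries. Of 19 mesenchymal genes, 7 rose and 9 fell, or 7 and 10 adjusted over the list alone (camera adjusted p of 0.788), against 4 and 7 with DESeq2 and 4 and 8 without GFP replicate 2. TGFBI rose by 0.59 ± 0.046, whereas the matrix metalloproteinase gene MMP2 changed by -1.19 ± 0.068 and PRRX1 by -0.91 ± 0.070. Of 20 matrix genes, 8 rose and 10 fell, over all genes and adjusted over the list alone (camera adjusted p of 0.534), with THBS1 at -1.09 ± 0.049, tenascin C (TNC) at -2.22 ± 0.13 and perlecan (HSPG2) at 0.71 ± 0.051.

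Signalling pathways held strong changes of single genes in both directions. Of 27 genes of the TGF-beta and BMP pathway, 15 rose and 5 fell, or 15 and 6 adjusted over the list alone, and the list did not pass (camera adjusted p of 0.0937). ID3 rose by 0.86 ± 0.055, CCN1 by 0.66 ± 0.045 and CCN2 by 0.72 ± 0.051. Of 23 WNT genes, 8 rose and 9 fell, or 4 and 7 with DESeq2 (camera adjusted p of 0.645), with a median of 0.02, a mean of -0.0061 and a test that pointed down. That median was -0.04 without GFP replicate 1, -0.13 without GFP replicate 2 and -0.10 without SALL4 replicate 2. SFRP1, a secreted WNT antagonist, changed by -1.78 ± 0.068, the WNT receptor gene FZD1 by -0.63 ± 0.060 and TCF7L1 by 0.84 ± 0.10. Of 17 Notch genes, 7 rose and 2 fell, or 7 and 3 adjusted over the list alone, 3 and 1 with DESeq2 and 5 and 1 without GFP replicate 1 (camera adjusted p of 0.484), with NOTCH1 at -0.69 ± 0.095 and HEY1 at 1.24 ± 0.20. Of 30 receptor tyrosine kinases and ligands, 9 rose and 8 fell, or 5 and 8 with DESeq2 and 6 and 8 without GFP replicate 2 (camera adjusted p of 0.784), with a median of 0.02, or -0.03 without SALL4 replicate 2, and a mean of -0.17. The ephrin gene EFNB2 changed by -1.55 ± 0.060, the ligand gene TGFA by -1.39 ± 0.058 and FGFR1 by 0.76 ± 0.049. Of 22 immediate early genes, 10 rose and 6 fell, or 12 and 7 adjusted over the list alone (camera adjusted p of 0.47), with EGR1 at 0.74 ± 0.048 and SPRY2 at -0.54 ± 0.053. The WNT and kinase counts were the same adjusted over the list alone.

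Lists of stress and metabolism gave calls in both directions as well. SCD, a fatty acid desaturase, changed by -0.74 ± 0.044, and 9 of 27 genes of cholesterol and fatty acid synthesis fell while 4 rose, or 10 and 4 adjusted over the list alone (camera adjusted p of 0.534, median of 0.0008 and mean of -0.08). The rises there dropped to 1 with DESeq2, without GFP replicate 1 and without GFP replicate 2, with 8, 9 and 8 falls, and numbered 6 with upper-quartile scaling, with 9 falls and a median of 0.05. The median was -0.03 without SALL4 replicate 1 and 0.03 without GFP replicate 1. SLC7A5, an amino acid transporter, rose by 0.79 ± 0.047 and the chaperone gene HSPA5 and the mTORC1 inhibitor gene DDIT4 changed by -0.38 ± 0.042 and -0.66 ± 0.082, among 8 rises and 5 falls in 24 stress response genes, or 8 and 7 adjusted over the list alone (camera adjusted p of 0.901). For that list the median of -0.0024 and the mean of 0.05 differed in sign, DESeq2 called 5 higher and 4 lower, and without GFP replicate 2 the counts were 5 and 5 and the median -0.08. TXNRD1 and FTL, both targets of NRF2, rose by 0.45 ± 0.043 and 0.44 ± 0.046, and UGDH fell, at -0.29 ± 0.051. Of 22 NRF2 targets 7 rose and 6 fell (camera adjusted p of 0.835), against 4 and 4 with DESeq2 and 5 and 2 without GFP replicate 2, where the median of 0.02 became -0.07, and 6 and 3 without GFP replicate 1, where it became 0.09. Of 24 cell cycle inhibitors and p53 targets, 6 rose and 6 fell (camera adjusted p of 0.784, median of -0.0034, mean of 0.06), with MDM2 at -0.31 ± 0.045, CDKN2B at -0.43 ± 0.071 and CDKN2D at -0.70 ± 0.12 among the falls and BTG2, an antiproliferative gene, at 1.28 ± 0.21 among the rises. DESeq2, and edgeR without GFP replicate 1, each called 5 of these higher and 3 lower, edgeR without GFP replicate 2 called 4 and 4, and without GFP replicate 2 or SALL4 replicate 2 the median was 0.05 or 0.06. H1299 lacks p53. Of 22 apoptosis regulators, 4 rose and 3 fell (camera adjusted p of 0.788), against 7 and 1 with upper-quartile scaling, 2 and 0 with DESeq2, 3 and 1 without GFP replicate 2 and 3 and 0 without SALL4 replicate 2. The NRF2, p53 and apoptosis counts were the same adjusted over the list alone.

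Immune genes other than the inflammatory list changed in part. HLA-C rose by 0.60 ± 0.056 and the immunoproteasome gene PSMB9 by 1.02 ± 0.15, and reads of HLA genes may be split among them. Of 16 antigen presentation genes, 6 rose and 2 fell, over all genes and adjusted over the list alone, or 4 and 1 with DESeq2 (camera adjusted p of 0.187). The RNA sensor gene DDX58 rose by 0.40 ± 0.096, and IFIT5 was called lower at -0.25 ± 0.077, a call that was lost with DESeq2, the GC correction, thinning and without GFP replicate 1, GFP replicate 2 or SALL4 replicate 2 (adjusted p from 0.0547 to 0.178). Of 23 interferon response genes 4 rose and 3 fell, or 4 and 2 adjusted over the list alone (camera adjusted p of 0.737). Those counts were 7 and 1 with upper-quartile scaling, 2 and 0 with DESeq2 and also without GFP replicate 2, and 4 and 0 without SALL4 replicate 2.

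Lineage genes showed no common direction. Among 19 neuronal and neuroendocrine genes, 5 rose and 9 fell, or 6 and 9 adjusted over the list alone and 3 and 9 without GFP replicate 1 (camera adjusted p of 0.534). The neurofilament gene NEFH rose by 1.07 ± 0.065, and the synaptic gene SNAP25 and the tubulin gene TUBB3 changed by -1.32 ± 0.093 and -0.59 ± 0.048. Of 10 lung lineage genes, 2 rose and 2 fell (camera adjusted p of 0.855), and the transcription factor genes SOX9 and ID2 changed by -0.86 ± 0.045 and 0.67 ± 0.098. The median of that list was 0.14, or -0.03 without SALL4 replicate 2, where 3 rose and 1 fell, and 2 rose and 1 fell with DESeq2 or without GFP replicate 1. Of 10 liver and endoderm oncofetal genes, 5 rose and 2 fell (camera adjusted p of 0.47), with IGF2BP1 at 0.38 ± 0.041 and IGF2BP3 at -0.53 ± 0.052. Of 15 transporters and drug-handling genes, 3 rose and 3 fell, or 1 and 2 with DESeq2 and 5 and 3 with upper-quartile scaling (camera adjusted p of 0.788), with ABCA1 at -0.53 ± 0.053 and ABCC5 at 0.60 ± 0.060. The lung, liver and transporter counts were the same adjusted over the list alone.

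Some markers of other cell types were higher with SALL4, and most others did not pass the count filter. Among fibroblast markers 3 of 10 were tested, and COL1A1 rose from 0.985 to 2.58 CPM, a log2 fold change of 1.39 ± 0.27, and THY1 from 1.12 to 1.94 CPM, while COL1A2, COL3A1 and DCN had at most 9 counts in a library and were named after their counts were seen. Of 14 immune cell markers 4 were tested, of which ITGAM, an integrin of myeloid cells, rose from 3.52 to 6.18 CPM, a log2 fold change of 0.77 ± 0.17, and CD68 rose as well, and 3 rose adjusted over the list alone. CD68, which many cell lines express, went from 55.1 to 61.6 CPM. PTPRC, the pan-leukocyte marker, named after its counts were seen, had 0 counts in all 4 libraries. Of 9 endothelial markers 3 were tested and 2 rose, ESAM from 0.896 to 1.68 CPM and CLDN5 from 0.684 to 1.30 CPM, and no red blood cell marker of 7 passed the count filter. DESeq2 called COL1A1 and ITGAM, with adjusted p of 0.0125 and 0.0173, and did not call THY1, CD68, ESAM or CLDN5, with adjusted p of 0.229, 0.165, 0.21 and 0.28. The endothelial count was 0 with DESeq2, without GFP replicate 2 and without SALL4 replicate 2, and 1 without either other library, and at least 1 fibroblast and 1 immune marker stayed called without any 1 library.

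The authors' deposited table of SALL4 against GFP holds 18332 genes, of which 3333 have an adjusted p under 0.05, 1471 higher and 1862 lower. Of these, 3323 were also called by edgeR here, all in the same direction, and 10 were not. The table was made from the same libraries and is not independent evidence. In the authors' deposited table SALL4 has a log2 fold change of 5.73, RSPO4 of 3.61, NPAS2 of -4.92 and IGFBP4 of -3.71. At least 2-fold changes are given there for 334 of the called genes.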

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

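The GC correction, thinning to equal depth and the 2-fold minimum were chosen after seeing the data. SALL4 stayed called in every setting run for it, with a log2 fold change from 5.63 to 5.82. DESeq2 called 3331 genes, 1464 higher and 1867 lower, all of them also called by edgeR, and the cause of the smaller number was not tested. It gave an adjusted p to 14645 genes, and its list medians cover only those. Its log2 fold changes differed from those of edgeR by a median of -0.00269. A list median that changed sign with DESeq2 may therefore reflect the members left out. A test against a log2 fold change of 1 called 139 genes, 66 higher and 73 lower, and a 2-fold minimum beside the adjusted p left 538, 324 higher and 214 lower, both by asking for larger changes. With the GC correction 5888 genes were called, 5139 of them also called without it. At least 2-fold calls shared with the authors' deposited table numbered 322. Without 1 library each in turn, where a lone library is assumed to vary like the other group, 4092 to 6020 genes were called, 1952 to 2809 higher and 2140 to 3211 lower. Of the lists, 0 passed with an estimated correlation, a test that also missed a simulated shift of -0.3 in genes drawn independently. With fry, which asks whether a list's genes move on balance and does not compare them with other genes, 17 passed. PDGFRB, not called at a log2 fold change of 0.53, ranged from -0.047 without SALL4 replicate 2 to 0.79 without SALL4 replicate 1, and the cause was not tested. Of 2204 values of named genes under the alternatives, 2153 kept direction and call, 49 lost the call, 1 gained it and 1, that of PDGFRB, reversed. The medians of the NuRD, p53 and stress response lists changed sign with upper-quartile scaling, those of the WNT, mesenchymal and pluripotency lists with DESeq2, those of the WNT, apoptosis and kinase lists with the GC correction (and, taken as differences of corrected log values, of the HOX and interferon lists, at -0.0079 and -0.015), and those of the cholesterol and stress response lists with limma-voom. Leaving out 1 library changed the sign of the medians of the pluripotency, earlier SALL4, WNT, NRF2, NuRD, p53, apoptosis, cholesterol, interferon, lung, kinase, stress response and transporter lists, none of which passed the list test.

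With the replicate number as a replicate block, 6294 genes were called, and the median of the stress response list, near 0, changed sign. Deviations of same-numbered libraries from their group means had a correlation of 0.0163 across genes, so no large effect shared by number was seen. This cannot show whether the libraries were paired, which the labels do not state.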

Other observations

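The gene families and RNA classes in this part, and all patterns weighed in it, were chosen after seeing the data. Genes of the mitochondrial ribosome were lower with SALL4, with 30 of 83 lower and 3 higher (camera adjusted p of 0.00223 over 9 families, adjusted p = 0.371 with an estimated correlation). With upper-quartile scaling 23 were lower and 7 higher. MRPS10 changed by -0.56 ± 0.058, MRPL36 by -0.51 ± 0.087 and MRPS2 by -0.33 ± 0.054. Among 6 S100 genes, which encode calcium-binding proteins, 3 fell and 0 rose (camera adjusted p of 0.00384, adjusted p = 0.242 with an estimated correlation), namely S100A16 at -1.59 ± 0.29, S100A10 at -0.67 ± 0.046 and S100A11 at -0.51 ± 0.065. Of 9 annexin genes, 4 fell and 0 rose (camera adjusted p of 0.0358, adjusted p = 0.29 with an estimated correlation), among them ANXA1 at -0.91 ± 0.050 and ANXA2, whose product binds that of S100A10, at -0.62 ± 0.042. With upper-quartile scaling the annexin p was 0.0563. Small nucleolar RNAs were higher, with 15 of 168 up and 4 down (camera adjusted p of 0.0263, 0.0947 with upper-quartile scaling, adjusted p = 0.242 with an estimated correlation). Of all genes tested, 38% were called. Medians were also above 0 for microRNAs (0.162), transcribed pseudogenes (0.131) and long non-coding RNAs (0.126), while that of small nuclear RNAs was -0.435. Whether abundance accounts for the rise of small nucleolar RNAs was not tested. The nuclear RNAs MALAT1 and NEAT1 rose by 1.23 ± 0.047 and 0.86 ± 0.044.

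Other families tested did not pass. Of 59 potassium channel genes, 13 rose and 7 fell (camera adjusted p of 0.285), with KCNMA1 at -0.56 ± 0.046. Of 18 ephrin and ephrin receptor genes, 3 rose and 7 fell (camera adjusted p of 0.0889), with EPHA4 at -2.60 ± 0.27. Of 10 laminin genes, 5 rose and 4 fell (camera adjusted p of 0.78), and of 16 tubulin genes, 3 rose and 6 fell (camera adjusted p of 0.166). Of 520 zinc-finger genes named ZNF, 60 rose and 78 fell (camera adjusted p of 0.166), with a median of -0.05. With upper-quartile scaling the balance turned, to 79 higher and 51 lower and a median of 0.0057.

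Genes of many chromosomes shifted together, 13 of 23 chromosomes (6 higher, 7 lower) passing an adjusted p of 0.05, and those with a shift of more than 0.1 on the log2 scale were weighed. Relative to all genes, the median log2 fold change was 0.14 on chromosome 5 (234 higher, 52 lower of 608), -0.18 on chromosomes 15 (36 and 198 of 410) and 18 (18 and 90 of 179) and -0.11 on chromosome 4 (44 and 167 of 473), each with a permutation p of 0.0001, the smallest that 10000 permutations can give, and 0.000192 adjusted over 23 chromosomes. Centring by transcript GC content left medians of 0.166, -0.17 and -0.153 on chromosomes 5, 15 and 18, which argues against GC content there, and -0.0573 (-0.0809 to -0.0376) on chromosome 4, which leaves it open. A whole-chromosome copy-number difference between the lines may account for part of the shift of chromosomes 5 and 15. There the least shifted of 4 equal segments of genes in map order was still at 0.124 (0.0891 to 0.163) and -0.0735 (-0.119 to -0.0359). The most shifted segments were at 0.252 (0.212 to 0.279) and -0.241 (-0.278 to -0.184), which an even difference alone would not give. On chromosomes 4 and 18 the least shifted segment was at -0.0237 (-0.0514 to 0.0268) and -0.0268 (-0.0645 to 0.0324), and the question stays open. The last segment of chromosome 18 was at -0.241 (-0.288 to -0.195), so its shift was uneven too. With 1 line per construct, an effect of SALL4 and a difference that arose between the lines were not separated. The list tests did not adjust for chromosome, so list members and named genes on a shifted chromosome may carry its shift.

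The log2 fold change rose with transcript GC content, with a rank correlation of 0.234 (0.216 to 0.25) across 11728 protein-coding genes, which are not independent replicates. Of 1179 genes with 31.0% to 39.8% GC, 115 were higher and 464 lower, and of 1171 with 61.8% to 74.2%, 334 and 166. The rank correlation with intron GC content was 0.218 (0.2 to 0.234), and 0.0182 (0.000125 to 0.0366) at fixed transcript GC content. The second value argues against regulation that follows intron composition apart from that of the transcript. It cannot decide on composition that introns and transcript share, since that is held fixed. A GC bias that differs from library to library may account for part of the trend, since the slopes of the SALL4 replicates differed by 0.739 of the difference between groups. Fragment GC content during library preparation stays open. It predicts no correlation with flanking DNA at fixed transcript GC content, and the rank correlation was 0.00422 (-0.0139 to 0.0236). Any effect of the transcript's own composition predicts the same, so this value cannot tell them apart. The slopes per 10% GC were -0.0303 and -0.0321 in the GFP libraries, which differed by only -0.0018, and 0.0081 and 0.0543 in the SALL4 libraries, both above both GFP values, so that a difference between the lines stays open.

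Long non-coding RNAs were higher with SALL4, with a median log2 fold change of 0.13 over 1312 genes, 189 higher and 73 lower, where protein-coding genes had a median of -0.01. Sequencing depth is argued against, since thinning to equal depth left a median of 0.0893 (0.0693 to 0.121) against 0.0976 before, both with 0.5 CPM added. Abundance rather than RNA class may account for the difference, since protein-coding genes of the same abundance differed from them by 0.02 (-0.00437 to 0.0505). Carry-over of genomic DNA or unspliced RNA stays open, with near-silent protein-coding genes at a SALL4 to GFP ratio of 1.06 (1.03 to 1.1). No biological explanation was tested.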
